A study of Homo sapiens with 10 samples.

How the data were processed

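BEAS-2B cells, an immortalized line of human bronchial epithelial cells, were profiled by RNA sequencing in 10 libraries. Total RNA was isolated with RNeasy columns and libraries were made with a TruSeq kit, per the labels' protocols. The libraries fall into 5 groups of 2. Untreated cells were kept at 10% O2 for 3 days, at 21% O2 for 3 days or at 10% O2 for 3 weeks, and cells given 150 µM H2O2 for 3 days were kept at 10% or at 21% O2. Cultures at 21% O2 stood in a NuAire incubator and those at 10% O2 in a Panasonic incubator, per the labels' protocols, so oxygen and incubator coincide in every oxygen comparison. The labels give the 2 libraries of each group the experiment numbers 1 and 2, the same as their replicate numbers. They do not say whether an experiment was a separate culture, or whether a number shared by groups marks a shared day, so p-values measure the spread between these samples.

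The authors deposited 1 table per library with read counts and RPKM for 25411 RefSeq gene symbols, per the file headers. Reads were aligned with STAR 2.4 to GRCh37 (hg19), and DESeq2 was also used, per the submitters' processing notes. The counting tool, the annotation version and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be separated. In 9194 of the 25411 lines a gene's several transcript identifiers spread over extra cells, so each line was read from its right end. All deposited counts were whole numbers, and the deposited RPKM values were not used. The tables hold no genes of the mitochondrial genome. Gene coordinates are those of the deposited tables.

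Total counts per library ran from 30251880 to 38748968. Counts were scaled by the trimmed mean of M values, with 30% of M values and 5% of A values trimmed at each end, and given as CPM, a gene's count per fixed number of counts in its library. A gene was tested when at least 2 libraries reached the CPM worth 10 counts in a library of median size and its total count was at least 15, which left 14532 genes. The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(CPM + 1), with 1 mean per group over all 10 libraries and 5 residual degrees of freedom. A fold change on this scale understates the change of genes with few counts. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05, chance alone gives about 727 of 14532 genes. The planned test, edgeR, and DESeq2, meant as a check on it, were not run, because the uneven lines kept the column from being accepted as counts. Limma-trend had been named before the data were examined, as were the 7 comparisons, but for files without counts. It was taken as the main test only after a limma-voom fit had been looked at, and each called 1 gene in the first comparison.

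The 7 comparisons were 21% against 10% O2 at 3 days, 3 weeks against 3 days at 10% O2, 21% O2 at 3 days against 10% O2 at 3 weeks, H2O2 against none at 10% O2, H2O2 against none at 21% O2, 21% against 10% O2 with H2O2, and the difference between the H2O2 responses at the 2 oxygen levels. Likewise, 40 gene lists with 994 members were fixed in advance, of which 980 members matched a symbol. The 35 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the 35 lists within a comparison, and again with a correlation estimated from the data and with fry. A list that passes camera moved relative to the other genes, so "higher" and "lower" of a list are meant in that sense. 5 lists could not be tested. Of the metallothioneins, alveolar cell markers and blood cell markers 4 members each passed the count filter, of the secretory and goblet cell markers 3, and of the mitochondrially encoded genes 0.

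The rule for naming genes was also fixed in advance. In the oxygen comparison at 3 days and in both H2O2 comparisons it takes the 10 genes with the largest positive and the 10 with the largest negative fold change among those with an adjusted p under 0.05, a mean of at least 2 CPM in the higher group and no overlap between libraries, and in each other comparison 5 and 5. It adds up to 4 members per list with an adjusted p under 0.05, and NFKB1, RELA, NFKBIA, IL6, CXCL8, CXCL1, IL1B, CCL2, ICAM1, PTGS2, SOD2, HMOX1, NQO1, CA9, VEGFA and CDKN1A whatever their p. PTGS2 did not pass the count filter. LOXL2 in the first comparison was the 1 other gene that the rule gave, so all other genes are named because they passed within a list alone or because their values stood out, and were chosen after their values were seen. The Y-linked genes and XIST were left out of all naming.

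Transcript length and GC content were taken as medians over the GENCODE transcripts of a symbol and were found for 92.9% of the tested genes. Alternatives fixed in advance were median-of-ratios size factors, no filter on low counts, limma-voom, a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. Pseudocounts of 0.25 and 4 CPM, library weights, a robust variance prior and a correction of the log2 values for length and GC content by loess (span 0.5) were added after the data had been seen, as were the oxygen and H2O2 effects averaged over 4 groups. The first comparison was also tested on simulated counts for the same 14532 genes. Of 100 genes changed 2-fold, 80% were recovered, and of 100 genes changed 4-fold, 92%, with 0 in the wrong direction and 10 false calls. Changed genes were drawn only from those with an expected count over 100, and no shifts shared by a library's genes were simulated. These shares therefore do not hold for all tested genes of the real data. A list made of the raised genes passed, and 0 of 30 lists of unchanged genes did. The simulated genes varied independently, so these lists cannot show how correlation between genes affects the list test.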

Results

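Gene expression was measured in 10 RNA-seq libraries of BEAS-2B bronchial epithelial cells, 2 per group, to ask whether the oxygen of ambient air by itself alters inflammatory transcription of the NF-kB1/RelA pathway. Each library held 30251880 to 38748968 counts, and 16541 to 17178 genes had at least 1 count. Log2 expression of the 2 libraries of a group correlated across genes at Pearson r 0.988 to 0.996, lowest in untreated cells at 21% O2 after 3 days. Genes are not independent replicates, so no p is given for these values.

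At 21% against 10% O2 after 3 days, the comparison nearest to the study's question, LOXL2 fell, and inflammatory targets of NF-kB and the heat shock genes were higher as groups. LOXL2, a lysyl oxidase that crosslinks collagen (chromosome 8, 23154411 to 23261722, hg19), went from 745 ± 50.3 CPM at 10% O2 to 351 ± 13.3 CPM at 21% O2 (SD, n = 2 each), a log2 change of -1.08 (SE 0.11, limma-trend adjusted p 0.0483). It was the 1 gene of 14532 that passed over all genes in this fit, which does not pair libraries by number. With the replicate number as a block 169 passed, but the labels do not say that the number marks a shared day or culture. Among 45 NF-kB target genes, 37 were higher and 8 lower at 21% O2, with a median fold of 1.34 (camera adjusted p 8.55e-06). All 17 heat shock genes were higher, with a median fold of 1.31 (camera adjusted p 8.55e-06), as were 21 of 24 unfolded protein response genes, with a median fold of 1.17 (camera adjusted p 0.000136). With the correlation between genes estimated from the data, the adjusted p of each of these 3 lists was 0.642. The 2 libraries at 21% O2 differed in size, since against the mean of the 10% O2 libraries the median log2 shift of the NF-kB targets was 0.12 in replicate 1 and 0.51 in replicate 2, and that of the heat shock genes 0.64 and 0.12. Replicate 2 was also the library with the higher shift of immediate early genes (1.68 against -0.56 in replicate 1) and of interferon-stimulated genes (0.61 against -0.27).

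Adjusted over the list alone, 9 NF-kB targets passed and all 9 were higher, against 0 over all genes. These were TNFRSF9, CXCL5, PTX3, CSF1, CD83, CXCL8, BIRC3, CXCL1 and NFKB1. TNFRSF9, a receptor induced in activated cells, went from 13.0 ± 0.268 to 31.5 ± 7.44 CPM (n = 2 each), with a log2 change of 1.20 (SE 0.17). CXCL8 went from 194 ± 5.76 to 490 ± 238 CPM, with a log2 change of 1.24 (SE 0.29, limma-trend adjusted p over all genes 0.125). Its value at 21% O2 rested on replicate 2, without which the log2 change was 0.72, against 1.75 without replicate 1. NFKB1 itself (chromosome 4, 103422487 to 103538459) went from 82.4 ± 10.4 to 111 ± 5.23 CPM, a log2 change of 0.43 (SE 0.12) with an adjusted p over all genes of 0.153. RELA had a log2 change of -0.21 (SE 0.08, adjusted p 0.256) and NFKBIA of 0.25 (SE 0.16, adjusted p 0.443). The 18 genes of the NF-kB and IkB proteins did not pass as a list (camera adjusted p 0.109), and REL passed within the list alone.

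Adjusted over the list alone, 4 heat shock genes passed (HSPB8, HSP90AA1, HSPH1 and DNAJB1), against 0 over all genes, and 1 unfolded protein response gene, HSPA5, with a log2 change of 0.51 (SE 0.11). Of 37 extracellular matrix genes 28 were lower (camera adjusted p 0.0159, and 0.642 with the estimated correlation), and 7 passed over the list alone, 6 lower and BGN higher, against 1 over all genes. COL5A1 was lower by a similar amount as LOXL2, at 117 ± 2.07 against 53.6 ± 3.28 CPM, a log2 change of -1.11 (SE 0.13, limma-trend adjusted p 0.0539). The cold-inducible RNA-binding protein gene RBM3 stood at 452 ± 114 CPM at 10% O2 and 166 ± 2.69 CPM at 21% O2, a log2 change of -1.42 (SE 0.18, adjusted p 0.0549). MERTK was higher, with a log2 change of 1.41 (SE 0.15, adjusted p 0.0510), and GREM1 lower, with a log2 change of -0.94 (SE 0.13, adjusted p 0.0549). In total 2497 genes had an unadjusted p under 0.05, and 126 an adjusted p under 0.10, 64 of them higher and 62 lower.

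In the other genes named in advance no difference passed. The log2 change was 0.96 (SE 0.68) for IL6, 0.21 (SE 0.41) for IL1B, 0.44 (SE 0.15) for CCL2, 0.09 (SE 0.17) for ICAM1, 0.61 (SE 0.22) for SOD2, 0.25 (SE 0.14) for HMOX1 and 0.22 (SE 0.23) for NQO1. For CA9 it was -2.10 (SE 0.84), for VEGFA -0.43 (SE 0.39) and for CDKN1A 0.63 (SE 0.63). Without replicate 2 at 21% O2, the change turned to -0.33 for IL6, -0.43 for IL1B and -0.03 for ICAM1. It turned to -0.27 for IL1B and -0.08 for ICAM1 without replicate 1 at 10% O2, and without replicate 1 at 21% O2 to -0.17 for NQO1 and 0.21 for VEGFA. Without replicate 2 and without replicate 1 at 21% O2 it was -3.66 and -0.54 for CA9, 0.11 and 1.14 for CDKN1A, 0.31 and 0.90 for SOD2 and 0.0719 and 0.43 for HMOX1. For NFKBIA it was 0.0759 without replicate 2 and 0.42 without replicate 1 at 10% O2.

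7 further lists passed camera at 21% against 10% O2 after 3 days. Higher were p53 targets (adjusted p 0.0259), amino acid response genes controlled by ATF4 (0.0407) and DNA repair genes (0.0407), and lower were ribosomal proteins (7.85e-05), glycolysis enzymes (0.000573), luminal keratins (0.0259) and HIF targets (0.0407). The adjusted p of all 11 lists by the estimated correlation lay between 0.642 and 0.757. The NF-kB target, heat shock and unfolded protein calls kept when any 1 library was left out, and the other 8 did not. Without replicate 1 at 21% O2 the adjusted p was 0.0954 for glycolysis, 0.106 for DNA repair and 0.116 for HIF targets, which then pointed upward. Without replicate 2 at 21% O2 it was 0.115 for ribosomal proteins, 0.682 for ATF4 genes, 0.428 for p53 targets, 0.0895 for matrix genes and 0.0864 for luminal keratins. Without replicate 1 at 10% O2 it was 0.446 for HIF targets, 0.217 for ATF4 genes, 0.0609 for p53 targets and 0.0630 for matrix genes, and without replicate 2 at 10% O2 0.152 for DNA repair and 0.0609 for luminal keratins.

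Fold changes of this comparison correlated across genes with transcript GC content (Spearman -0.497 over 13499 genes). After correction for length and GC content LOXL2 had a log2 change of -0.92 (SE 0.14, adjusted p 0.0706) and 0 genes passed with limma-trend, 1805 having an unadjusted p under 0.05, while the NF-kB target list passed at 1.94e-08 and the DNA repair list did not (0.172). The limma-voom fit without that correction called 1 gene. When single libraries were left out, 0 to 55 genes passed. The count was 31 without replicate 1 and 55 without replicate 2 of the untreated 21% O2 cells, and 0 without any 1 of the untreated 10% O2 libraries of 3 days or 3 weeks or of the H2O2 libraries at 21% O2.

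**Figure D1:**
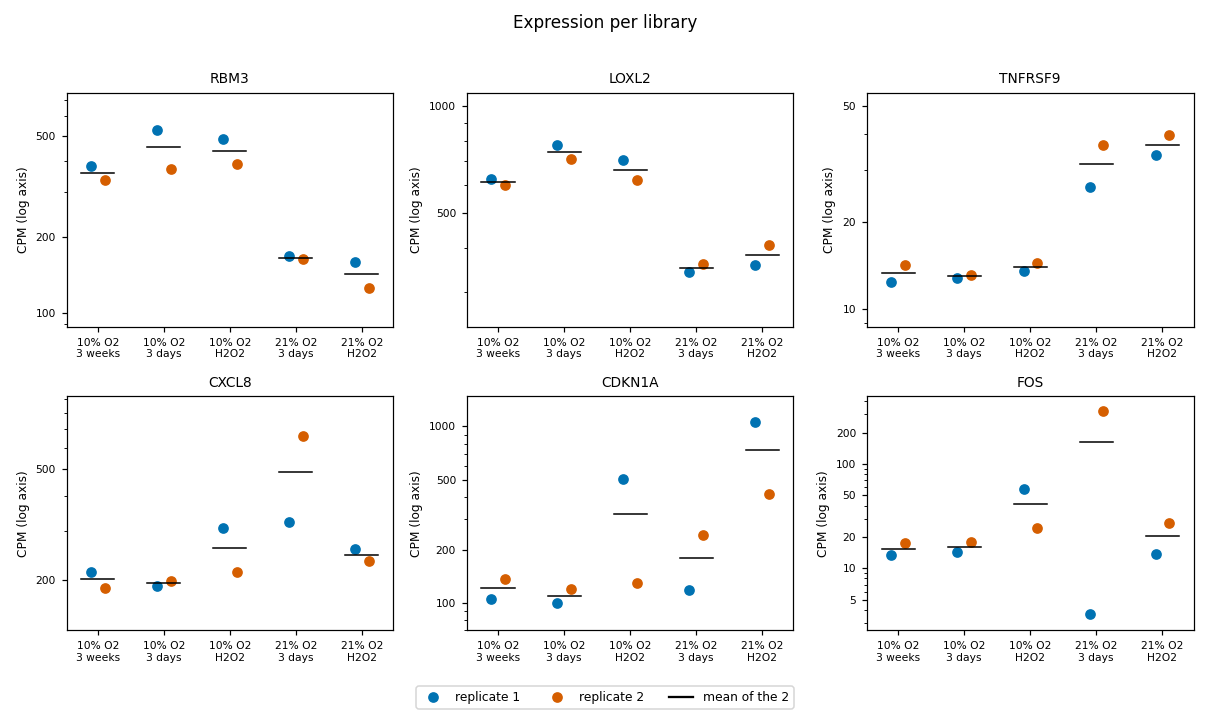
CPM on a log axis of 6 genes in each of the 10 libraries, by group, with points for the replicates and lines for the mean of the 2. LOXL2 and RBM3 were lower and TNFRSF9 higher in all 4 libraries at 21% O2 than in all 6 at 10% O2, while CXCL8, CDKN1A and FOS differed widely between replicates in some groups.

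After 3 weeks against 3 days at 10% O2, which asked what longer culture at the lower oxygen changes, ribosomal protein genes were lower as a group and no single gene passed. The 40 ribosomal protein genes had a median fold of 0.912 (camera adjusted p 2.17e-09, and 0.960 with the estimated correlation), and the call kept when any 1 library was left out. NFKB1 stood at 76.8 ± 4.10 CPM against 82.4 ± 10.4 CPM (n = 2 each), a log2 change of -0.10 (SE 0.12, limma-trend adjusted p 0.957) that became 0.0316 without replicate 1 of 3 days. RELA had a log2 change of -0.14 (SE 0.08), or -0.0893 without replicate 2 of 3 weeks. ATM passed within the DNA repair list alone, with a log2 change of 0.55 (SE 0.08), against 0 over all genes. The limma-trend fit called 0 genes, 629 had an unadjusted p under 0.05, and limma-voom also called 0.

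4 other lists were lower after 3 weeks, with adjusted p of 0.749 to 0.960 by the estimated correlation, and each call ended without 1 of the 3-day libraries. These were cholesterol synthesis (camera adjusted p 1.26e-08, and 0.571 without replicate 1), nuclear-encoded oxidative phosphorylation (0.00125, and 0.0642 without replicate 1), antioxidant enzymes (0.0219, and 0.306 without replicate 1) and glycolysis (0.00502, and 0.0797 without replicate 2).

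At 21% O2 after 3 days against 10% O2 after 3 weeks, a comparison that mixes oxygen with culture time, heat shock and unfolded protein response genes were again higher as groups. All 17 heat shock genes were higher, with a median fold of 1.38 (camera adjusted p 1.88e-08), and 8 passed over the list alone, among them HSP90AA1 with a log2 change of 1.23 (SE 0.27) and HSPH1 with 1.03 (SE 0.26, or 0.64 without replicate 1 at 21% O2), against 0 over all genes. Unfolded protein response genes had a median fold of 1.19 (camera adjusted p 2.19e-05) and antioxidant enzymes of 1.15 (camera adjusted p 0.0322). These 3 calls kept when any 1 library was left out, and their adjusted p with the estimated correlation was 0.394.

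NF-kB targets had a median fold of 1.26 against the cells of 3 weeks (camera adjusted p 5.27e-05, and 0.394 with the estimated correlation). 9 of the 45 passed over the list alone, all higher, against 0 over all genes, with PTX3 at a log2 change of 1.68 (SE 0.24) and TNFRSF9 at 1.17 (SE 0.17). NFKB1 stood at 111 ± 5.23 against 76.8 ± 4.10 CPM, a log2 change of 0.52 (SE 0.12, limma-trend adjusted p 0.183), and CXCL8 had a log2 change of 1.20 (SE 0.29), or 0.69 without replicate 2 at 21% O2. Genes of the NF-kB and IkB proteins passed too (camera adjusted p 0.00586), as did p53 targets (0.00586), matrix genes, which were lower (0.00400), and oxidative phosphorylation (0.0413), with adjusted p of 0.394 to 0.784 by the estimated correlation. Without replicate 2 at 21% O2 the adjusted p was 0.110 for NF-kB targets, 0.111 for NF-kB and IkB proteins, 0.273 for p53 targets and 0.0784 for matrix genes. That of oxidative phosphorylation was 0.718 without replicate 1 at 21% O2, then downward, and 0.0885 without replicate 1 of 3 weeks, and 0.0718 after the length and GC correction. LOXL2 (-0.80, SE 0.11) and COL5A1 (-1.01, SE 0.13) had negative log2 changes, both with an adjusted p of 0.108. The limma-trend fit called 0 genes, 2379 had an unadjusted p under 0.05, and limma-voom called 0. Without replicate 1 or replicate 2 at 21% O2, limma-trend called 17 and 90.

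H2O2 at 10% O2 asked for the response to added peroxide at the lower oxygen level. Only the extracellular matrix list, which was lower, kept its call when any 1 library was left out. Of 37 matrix genes 24 were lower, with a median fold of 0.890 (camera adjusted p 6.03e-05, and 0.613 with the estimated correlation). Most of its size came from H2O2 replicate 1, with a median log2 shift of -0.27 against -0.069 in replicate 2. COL5A1 stood at 78.7 ± 7.52 CPM with H2O2 against 117 ± 2.07 CPM without (n = 2 each), a log2 change of -0.57 (SE 0.13, limma-trend adjusted p 1.00). CCL2 had a log2 change of -0.45 (SE 0.15), or -0.22 without H2O2 replicate 1, and NFKB1 of -0.11 (SE 0.12), which became 0.0201 without untreated replicate 1 and 0.0327 without H2O2 replicate 2. The limma-trend fit called 0 genes, 145 had an unadjusted p under 0.05, fewer than the 727 of chance, and limma-voom called 0. Replicate differences of these 2 groups correlated at 0.678, and a fit that does not pair libraries keeps them in its spread. The 0 calls therefore do not show that H2O2 changed nothing, though with the replicate number as a block 0 genes passed as well. No list had a member that passed over the list alone.

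9 other lists passed camera with H2O2 at 10% O2, and each call depended on 1 library. By the estimated correlation none passed, with adjusted p from 0.613 to 0.913, that of p53 targets being 0.803. p53 targets were higher (adjusted p 3.88e-08, 27 of 28 genes), but CDKN1A read 503 CPM in replicate 1 and 130 CPM in replicate 2, and without replicate 1 the list pointed downward at an adjusted p of 0.551. S phase genes were lower (3.90e-18, 38 of 40 genes, and 0.324 without that replicate) and interferon-stimulated genes higher (9.13e-06, and 0.432 and downward without it). Mitosis genes were higher (3.03e-08) and HIF targets higher (0.0220), yet without H2O2 replicate 1 both were lower, at 0.0298 and 0.0185, and without untreated replicate 2 they stood at 0.436 and 0.834. Cholesterol synthesis was lower in 25 of 25 genes (2.10e-14, and 0.770 without untreated replicate 1). Immediate early genes were higher (6.81e-06) and fatty acid synthesis lower (0.000780), with 0.147 and 0.236 without untreated replicate 1 and 0.157 and 0.568 without H2O2 replicate 1. Fibroblast markers were lower (0.0220), with 0.242 and 0.141 without untreated replicate 1 or 2, 0.0919 without replicate 2 of 3 weeks and 0.482 without H2O2 replicate 1.

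H2O2 at 21% O2 asked the same at ambient oxygen, and p53 targets were higher and cholesterol synthesis genes lower as groups. Of 28 p53 targets 25 were higher, with a median fold of 1.33 (camera adjusted p 1.86e-08, and 0.544 with the estimated correlation). Their median log2 shift from untreated cells at 10% O2 was 0.86 and 0.37 in H2O2 replicates 1 and 2. It was 0.13 and 0.37 in untreated replicates 1 and 2, so the list median was no higher in H2O2 replicate 2 than in untreated replicate 2. Single members could differ from the median, as CDKN1A read 412 CPM in H2O2 replicate 2 and 241 CPM in untreated replicate 2. Members going the other way were not counted. GDF15, a stress-induced cytokine of the TGF-beta family, passed over the list alone, against 0 over all genes. GDF15 stood at 20.1 ± 6.92 CPM with H2O2 against 2.22 ± 0.412 CPM without (n = 2 each), a log2 change of 2.68 (SE 0.46, limma-trend adjusted p 0.530), and CDKN1A had a log2 change of 1.97 (SE 0.63), or 1.28 without H2O2 replicate 1. Of 25 cholesterol synthesis genes 24 were lower, with a median fold of 0.783 (camera adjusted p 1.40e-08, and 0.420 with the estimated correlation). All 17 glycolysis enzymes were higher, with a median fold of 1.20 (camera adjusted p 1.68e-08, and 0.420 with the estimated correlation), and 4 passed over the list alone, against 0 over all genes. Their median log2 shift was -0.0032 and 0.13 in H2O2 replicates 1 and 2 and -0.38 and -0.12 in the untreated ones. With H2O2 the list thus lay near untreated cells at 10% O2, and the untreated 21% O2 libraries lay low.

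DNA repair genes (camera adjusted p 1.08e-07) and S phase genes (1.42e-05) were also lower with H2O2 at 21% O2, and basal airway cell markers (2.47e-07) and luminal keratins (0.000736) higher. These 4 calls and the 3 before kept when any 1 library was left out, and with the estimated correlation their adjusted p was 0.347 to 0.605. The luminal keratins shifted by 0.029 and 0.084 in H2O2 replicates 1 and 2, against -0.23 and -0.28 in the untreated ones. The same untreated libraries gave the lower glycolysis and luminal keratin values at 21% against 10% O2, so those results are not separate evidence. The basal marker NGFR went from 1.03 ± 0.461 to 3.79 ± 0.0624 CPM, a log2 change of 1.25 (SE 0.17), and THBS1, a matrix glycoprotein and TGF-beta target, from 442 ± 100 to 125 ± 31.7 CPM, a log2 change of -1.82 (SE 0.27), each with a limma-trend adjusted p of 0.377. CXCL8 (-0.90, SE 0.29), CXCL1 (-0.47, SE 0.13) and CCL2 (-0.60, SE 0.15) had negative log2 changes that did not pass. Without untreated replicate 1 and without untreated replicate 2 the change was -1.41 and -0.39 for CXCL8 and -0.63 and -0.30 for CXCL1. The limma-trend fit called 0 genes, 963 had an unadjusted p under 0.05, and limma-voom called 0. The limma-trend count changed without untreated replicate 1 or without H2O2 replicate 2.

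The other 12 lists that passed with H2O2 at 21% O2 depended on single libraries, and by the estimated correlation the adjusted p of all 19 lay between 0.347 and 0.725. Without untreated replicate 2, NF-kB targets (lower, camera adjusted p 0.0147) stood at 0.841 and pointed upward, ribosomal proteins (higher, 0.000502) at 0.590, and immediate early genes (lower, 0.0101) passed the other way at 1.77e-06. Those immediate early genes stood at 0.108 without H2O2 replicate 2. Without untreated replicate 1, HIF targets (higher, 4.12e-07) stood at 0.904 and heat shock genes (lower, 0.00762) at 0.815, both then the other way, proteases and inhibitors (higher, 0.0168) at 0.175, and mitosis genes (lower, 1.66e-05) at 0.308, the last also at 0.310 without H2O2 replicate 1. ATF4 genes (lower, 0.000736), TGF-beta targets (lower, 0.0233) and fatty acid synthesis (lower, 0.00435) stood at 0.497, 0.148 and 0.107 without untreated replicate 2. Of these, ATF4 genes and TGF-beta targets stood at 0.165 (then upward) and 0.0801 without H2O2 replicate 2, and fatty acid synthesis at 0.0850 without H2O2 replicate 1. NADPH oxidase genes (higher, 0.0187) and epithelial junction genes (higher, 0.0372) stood at 0.2503 and 0.904 without untreated replicate 1 and at 0.0740 and 0.144 without H2O2 replicate 2. Across genes, the fold changes correlated with GC content at a Spearman value of 0.433.

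At 21% against 10% O2 with H2O2, which asked whether the oxygen difference recurs in treated cells, mitosis genes were lower and epithelial junction genes and basal airway cell markers higher as groups. The 40 mitosis genes had a median fold of 0.793 (camera adjusted p 1.00e-11), the junction genes of 1.14 (0.00128) and the basal markers of 1.18 (0.0134). These calls kept when any 1 library was left out, and with the estimated correlation the adjusted p was 0.802 for each. The mitosis difference lay mostly in the replicate 1 libraries, with a median log2 shift of -0.31 at 21% O2 and 0.37 at 10% O2. In replicate 2 the shifts were -0.0904 and -0.0608. RBM3 stood at 143 ± 24.2 against 439 ± 69.1 CPM (n = 2 each), a log2 change of -1.62 (SE 0.18), COL5A1 had a log2 change of -1.09 (SE 0.13), TNFRSF9 of 1.33 (SE 0.17) and LOXL2 of -0.79 (SE 0.11), each with a limma-trend adjusted p of 0.119. The limma-trend fit called 0 genes, 1770 had an unadjusted p under 0.05, and limma-voom called 0.

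NF-kB targets were higher at 21% O2 with H2O2 (camera adjusted p 0.0192, and 0.802 with the estimated correlation), with a median fold of 1.05, and 3 of 45 passed over the list alone, 2 higher and 1 lower, against 0 over all genes. Without H2O2 replicate 2 at 10% O2 their adjusted p was 0.0808. By the estimated correlation the adjusted p of the 12 lists lay between 0.802 and 0.914. Leaving out H2O2 replicate 2 at 10% O2 also ended the calls of NF-kB and IkB proteins (higher, 0.0270, then 0.308), unfolded protein response (higher, 0.000113, then 0.0756), p53 targets (higher, 5.73e-06, then 0.263), apoptosis regulators (higher, 0.0137, then 0.454) and heat shock genes (higher, 0.0492, then 0.372). Without replicate 1 at 21% O2 the adjusted p was 0.144 for NF-kB and IkB proteins, 0.160 for p53 targets, 0.196 for apoptosis regulators, 0.0520 for heat shock genes and 0.144 for cholesterol synthesis, which was lower at 0.00611 with all libraries. Heat shock genes stood at 0.0785 without replicate 2 at 21% O2. Immediate early genes (lower, 0.0273) stood at 0.436 without replicate 1 at 10% O2 and at 0.0994 without replicate 2 at 21% O2. Ribosomal proteins (lower, 0.0492) did not pass without any 1 of 7 libraries, the highest values being 0.338 without replicate 2 at 21% O2 and 0.308 without replicate 2 at 10% O2, nor after the length and GC correction (0.109). HMOX1 (0.54, SE 0.14), SOD2 (0.77, SE 0.22) and HSPA5 (0.66, SE 0.11) had positive log2 changes that did not pass over all genes, and SOD2 stood at 0.48 without replicate 1 at 10% O2.

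The difference between the H2O2 responses at 21% and 10% O2 had its smallest p in the mitosis list, whose 40 genes all had a more negative mean response at 21% O2. The median difference was -0.30 on the log2 scale (camera adjusted p 3.50e-13, and 0.728 with the estimated correlation), and the call kept when any 1 library was left out. The difference lay in the replicate 1 libraries, where the median log2 shift with H2O2 was -0.31 at 21% O2 and 0.37 at 10% O2, against 0.11 in both untreated ones. In replicate 2 it was -0.0904 and -0.0608 with H2O2, against -0.15 and -0.11 untreated. THBS1 had a difference of -1.69 (SE 0.38), CXCL8 of -1.30 (SE 0.41), NGFR of 0.96 (SE 0.24) and GDF15 of 1.24 (SE 0.65), each with a limma-trend adjusted p of 1.00. Without untreated replicate 1 and without untreated replicate 2 at 21% O2 the difference was -1.81 and -0.79 for CXCL8, and GDF15 had 0.51 without H2O2 replicate 2 and 1.98 without H2O2 replicate 1 at 10% O2. THBS1 passed within the TGF-beta list alone and NGFR within the basal marker list alone. Another 13 lists passed camera, all of them dependent on single libraries, and ribosomal proteins did not pass after the length and GC correction (0.0965). The limma-trend fit called 0 genes, 188 had an unadjusted p under 0.05, fewer than the 727 of chance, and limma-voom called 0. The limma-trend count changed without untreated replicate 1 at 21% O2.

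Log2 changes between 21% and 10% O2 with and without H2O2, which share no library, correlated across 14532 genes at Pearson r 0.587 (covariance 0.0445, against a mean r of 0.000673 in 100 simulations of unchanged groups). Those simulations drew every library independently, whereas replicate differences of the untreated and H2O2 groups at 10% O2 and 3 days correlated at 0.678. They cannot show how much of r such shared differences give. The correlation of the oxygen changes was 0.331 without H2O2 replicate 2 at 10% O2 and at least that without any other library. H2O2 responses at 10% and at 21% O2 correlated at r 0.252 (covariance 0.00930), and at -0.0661 without untreated replicate 1 at 10% O2. The change from 10% O2 at 3 weeks to 21% O2 at 3 days correlated with the H2O2 response at 10% O2 at r 0.1004 (covariance 0.00483), and at -0.395 without H2O2 replicate 1, and it was also below 0 without untreated replicate 2 of either oxygen level at 3 days. The highest value with a library left out was 0.473. The oxygen change at 3 days and the H2O2 response at 10% O2 share their controls. Their r was 0.232 against a simulated 0.501, and their covariance 0.0102 against a simulated 0.0174, and r was -0.0968 without H2O2 replicate 1. The 2 controls could not be split with at least 2 libraries on each side. Shared controls alone gave more than the observed value in the simulations. Those simulations again left out the replicate differences that the 2 groups at 10% O2 share. The value therefore does not decide on agreement beyond the shared controls.

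**Figure D2:**
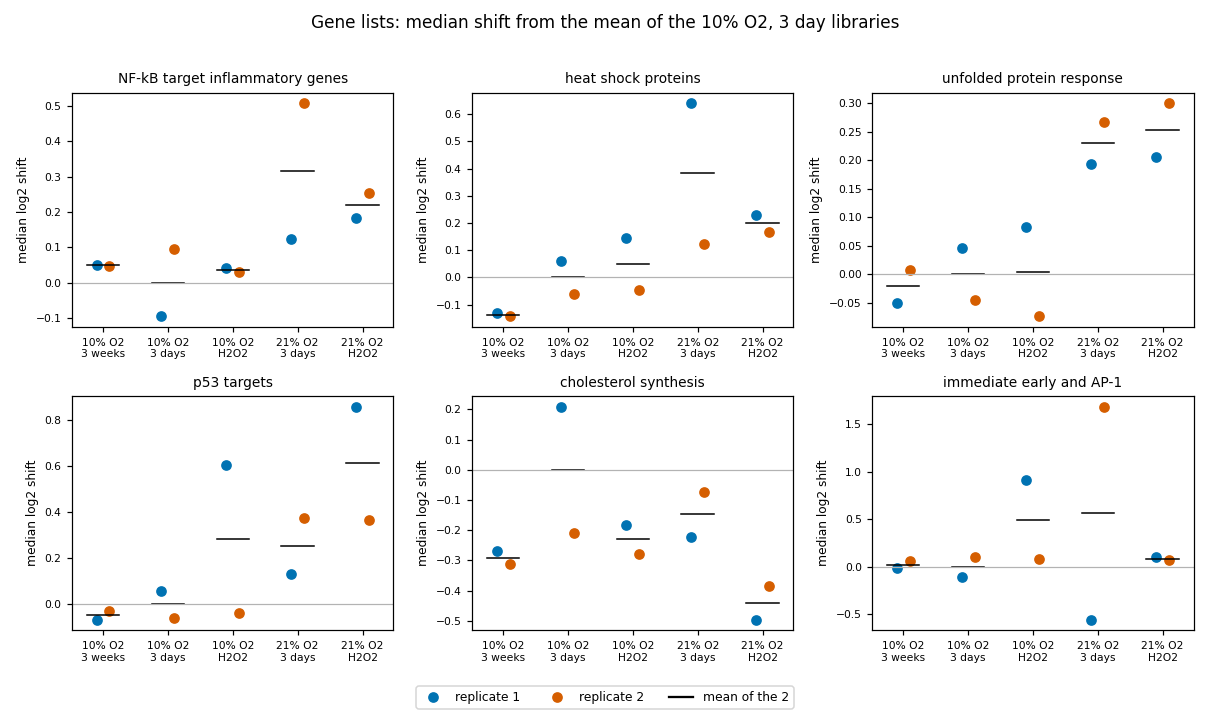
Median log2 shift of 6 gene lists in each of the 10 libraries from the mean of the untreated 10% O2 libraries of 3 days, by group, with points for the replicates and lines for their mean. The unfolded protein and NF-kB target lists lay higher in all 4 libraries at 21% O2 than in all 6 at 10% O2. For the NF-kB targets the margin was small, with a lowest shift of 0.12 at 21% O2 and a highest of 0.096 at 10% O2. The immediate early list reached 1.68 in 1 untreated library at 21% O2 and -0.56 in the other.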

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

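Of the tests in this part, the one on the oxygen score of the untreated 21% O2 libraries was chosen after the result was seen. In a test of the difference between the H2O2 responses at 21% and 10% O2, the interaction term of the model, 14 gene lists passed camera at the preset correlation, with adjusted p from 3.50e-13 for mitosis to 0.0388 for p53 targets. None of the 14 passed with the estimated correlation, where the adjusted p lay between 0.728 and 0.836, and none passed with fry for a shared direction. As median log2 differences of the response at 21% minus that at 10% O2, lower values were found for immediate early genes (-1.16), mitosis (-0.30), interferon-stimulated genes (-0.30), ATF4 genes (-0.23), heat shock proteins (-0.22), NF-kB targets (-0.15) and DNA repair (-0.0917). Higher values were found for basal airway cell markers (0.48), luminal keratins (0.38), HIF targets (0.27), glycolysis (0.19), epithelial junction genes (0.19), p53 targets (0.18) and ribosomal proteins (0.0629). Mitosis was the 1 list whose call kept when any 1 library was left out, and its difference lay in the replicate 1 libraries.

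Untreated 21% O2 libraries ended most of the other 13 calls. Without replicate 1 the adjusted p was 0.0893 for HIF targets, which then pointed downward, 0.0565 for glycolysis, 0.847 for heat shock proteins, 0.796 for p53 targets, 0.766 for junction genes and 0.0893 for basal markers. Without replicate 2 it was 0.659 for NF-kB targets, 0.540 for interferon-stimulated genes and 0.496 for immediate early genes, which both then pointed upward, 0.659 for ATF4 genes, 0.892 for ribosomal proteins and 0.0759 for luminal keratins. Without untreated replicate 1 at 10% O2 it was 0.463 for NF-kB targets, 0.325 for HIF targets, 0.115 for ATF4 genes, 0.414 for p53 targets, 0.161 for junction genes and 0.138 for ribosomal proteins. Without H2O2 replicate 1 at 10% O2 it was 0.407 for interferon-stimulated genes, 0.0942 for ribosomal proteins and 0.141 for luminal keratins. Without H2O2 replicate 2 at 10% O2 it was 0.695 for HIF targets and 0.192 for p53 targets, which both then pointed downward, 0.132 for glycolysis and for ATF4 genes, 0.145 for DNA repair and 0.191 for junction genes. Without H2O2 replicate 1 at 21% O2 it was 0.346 for p53 targets, then downward, and 0.151 for ribosomal proteins, and without replicate 2 there 0.181 for ATF4 genes, then upward, and 0.0729 for junction genes.

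The immediate early genes were far apart between the 2 untreated 21% O2 libraries, with FOS at 3.63 CPM in replicate 1 and 321 CPM in replicate 2, and EGR1 at 56.5 and 2888 CPM. GC and length bias is argued against, since the median log2 difference of the 27 genes was 2.28 before and 2.20 after the correction. A score was taken over the 100 genes that separate the H2O2 libraries by oxygen. On it the lower of the 2 libraries exceeded the untreated 10% O2 libraries by 2.21 times their range. The genes were picked by p-values that drew on the spread within all groups, which favours genes on which these 2 libraries agree. The score therefore does not decide whether 1 of them is a mislabelled 10% O2 library. Over all genes replicate 1 correlated best with untreated replicate 1 at 10% O2 (r 0.991, against 0.988 with its own replicate). A difference in how long before harvest the medium was changed or the dish handled may explain such a burst, and stays open. The design names no difference between the 2 replicates, so no biological explanation was tested.

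The p53 response was present in 1 of the 2 H2O2 libraries at 10% O2, with a median shift of the list of 0.61 in replicate 1 and -0.04 in replicate 2. GC and length bias is argued against, since the median difference between the 2 libraries was 0.60 before and 0.58 after the correction. On a score of genes that respond to H2O2 at 21% O2, replicate 2 exceeded all untreated 10% O2 libraries by 1.06 times their range. These genes too were picked by p-values that drew on the spread within all groups. That favours genes on which the H2O2 replicates at 10% O2 agree, so the score does not decide whether replicate 2 is an untreated library. Untreated replicate 2 at 10% O2 was the library that H2O2 replicate 2 correlated with best (r 0.998). H2O2 replicate 1 likewise correlated best with untreated replicate 1 at 10% O2 (r 0.995), so such a match is not particular to replicate 2. At 21% O2 the median of the p53 list also lay no higher with H2O2 than without in replicate 2 (0.37 each), against 0.86 and 0.13 in replicate 1. That holds for the median only, since CDKN1A read 412 CPM with and 241 CPM without H2O2 in replicate 2, and GDF15 15.2 and 2.51 CPM. Members going the other way were not counted. A weaker exposure or an earlier recovery of the replicate 2 culture at 10% O2 may explain the gap there and stays open. No biological explanation was tested, as the design gives none for a difference between replicates.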

How the results depend on the processing

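The pseudocounts, library weights, robust prior, length and GC correction and average effects were tested only after the data had been seen. The planned edgeR and DESeq2 fits were not run. For 21% against 10% O2 at 3 days, where 1 gene passed, limma-voom also called 1, and 3 genes passed with median-of-ratios size factors, 7 with a pseudocount of 0.25 CPM, 2 with 4 CPM, and 21 with a robust variance prior. 0 passed without the filter on low counts, with library weights, with the length and GC correction, and with only the compared groups. LOXL2 kept a log2 change between -1.15 and -0.92 throughout, and with the correction its change shrank to -0.92 while its SE went from 0.11 to 0.14, which ended the call. Leaving out single libraries gave 0 to 55 genes. A group left with 1 library was assumed to vary like the others.

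For 21% O2 at 3 days against 10% O2 at 3 weeks, 0 genes became 1 with a pseudocount of 0.25 CPM, 2 with only the compared groups, and 0 to 90 when single libraries were left out. For H2O2 at 21% O2, 0 became 1 with a pseudocount of 0.25 CPM and 0 to 10 without single libraries, for the interaction 0 to 6, and for the average H2O2 effect 0 to 4. The average oxygen effect gave 734 genes, against 390 without the filter, 318 with library weights, 102 with only the compared groups, and 3 to 673 without single libraries. H2O2 at 10% O2 and 3 weeks against 3 days stayed at 0 under all alternatives run. Libraries outside a comparison change its count mainly through the shared variance estimate and its degrees of freedom. LOXL2 at 21% against 10% O2, for example, kept a log2 change of -1.08 without either library of 3 weeks. The cause of the other differences was not tested.

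Of 79 list calls, 77 kept with median-of-ratios factors and 75 with the length and GC correction, but 0 passed with the estimated correlation and 0 with fry for a shared direction. Fry for changes in either direction within a list passed 9 lists for 21% against 10% O2 at 3 days, 9 against 3 weeks, 1 for H2O2 at 21% O2, 7 for 21% against 10% O2 with H2O2, 15 for the average oxygen effect and 0 in the other comparisons. 19 kept when any 1 library was left out and 60 ended without at least 1, 3 of them passing the other way. Among gene values, 1859 kept their direction and side of the threshold, 37 no longer passed and 54 newly passed. 10 reversed, each when a single library was left out. At 3 days these log2 changes ranged from -0.33 to 2.24 for IL6, -0.43 to 0.85 for IL1B, -0.0755 to 0.26 for ICAM1, -0.17 to 0.61 for NQO1 and -1.07 to 0.21 for VEGFA. For NFKB1 they ranged from -0.22 to 0.0316 for 3 weeks against 3 days and from -0.25 to 0.0327 for H2O2 at 10% O2. The correlations between comparisons ranged from 0.331 to 0.646 (oxygen with and without H2O2), -0.0661 to 0.416 (H2O2 at both oxygen levels), -0.395 to 0.473 (21% O2 against 3 weeks, and H2O2 at 10% O2) and -0.0968 to 0.608 (oxygen, and H2O2 at 10% O2). The cause was not tested.

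With the replicate number as a block, 169 genes passed for 21% against 10% O2 at 3 days, 167 against 3 weeks, 5 with H2O2, and 1613 for the average oxygen effect, and 74 of the 79 list calls kept. The labels carry an experiment number equal to the replicate number but do not say that it marks a shared day, batch or culture. Replicate differences correlated above 0.1 in 7 of the 10 pairs of groups and not in all (lowest 0.0006, highest 0.678), so the numbers were not taken to pair the libraries. All 10 libraries deviated from their group mean most like a library of their own number, a hint from the data that mirrors itself with 2 libraries per group. The block calls had been seen when this was written down, and if the experiment number does mark a shared culture or day, the 169 genes rather than 1 would apply.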

Other observations

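The tests of the average oxygen and H2O2 effects were chosen after the result of the single comparisons was seen. The average of the oxygen changes with and without H2O2 gave 398 genes higher and 336 lower at 21% O2 with limma-trend. RBM3 fell, with a log2 change of -1.52 (SE 0.13, adjusted p 0.00584), as did COL5A1 (-1.10, SE 0.09) and LOXL2 (-0.94, SE 0.07), and TNFRSF9 rose by 1.27 (SE 0.12). HSPA5 rose by 0.58 (SE 0.08), HSPB8 by 1.07 (SE 0.19), MERTK by 1.20 (SE 0.11) and SOD2 by 0.69 (SE 0.16, adjusted p 0.0455), while NFKB1 did not pass (0.31, SE 0.09, adjusted p 0.0751). Over the list alone 15 of 45 NF-kB targets passed, 14 of them higher, against 7 over all genes. The genes named here were chosen after their values were seen. The count of 734 genes depended on single libraries, for a cause that was not tested, being 3 without H2O2 replicate 2 at 21% O2, 14 without replicate 1 there, 29 without untreated replicate 2 at 10% O2, 150 without H2O2 replicate 2 at 10% O2, 485 without untreated replicate 1 at 21% O2, and 107 and 102 without replicate 1 or 2 of 3 weeks. The design explains part of this, since the libraries of 3 weeks lie on neither side of the average oxygen effect. They enter it mainly through the shared variance estimate and its degrees of freedom. With only the compared groups 102 genes passed. Of the 614 genes that passed after the length and GC correction, 452 were among the 734. The average H2O2 effect called 0 genes with limma-trend and with limma-voom, and 798 had an unadjusted p under 0.05. GDF15 had the log2 change 2.06 (SE 0.32, adjusted p 0.519) and CCL2 -0.52 (SE 0.11).

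The tests of the average oxygen effect below were written before their results were seen, on a pattern found in the same data. Among the 35 splits of the 8 libraries of 3 days into 4 and 4, the oxygen split called 726 genes and 1 split, the oxygen split itself, called as many, the highest of the others being 1. The count of the average oxygen effect, from the same libraries, had been seen before this test, so a high count of the oxygen split was nearly fixed. The test therefore does not decide on a chance difference, and 1 of 35 is the smallest share it can give. RBM3 was lower at 21% O2, and heat shock genes were higher by camera at the preset correlation (adjusted p 0.000183) but not at the estimated one (0.705). A candidate explanation is a lower temperature in the incubator at 10% O2. CIRBP, the other cold-inducible RNA-binding protein gene, had an average oxygen change of -0.65 (SE 0.09, adjusted p 0.0163), the direction that a temperature difference needs. Length and GC bias is argued against, since RBM3 kept -1.47 (SE 0.14) after the correction. Oxygen itself stays an open explanation, and oxygen and incubator cannot be told apart because every culture at 21% O2 stood in one incubator and every culture at 10% O2 in the other.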
